A study of Rattus norvegicus with 12 samples.

How the data were processed

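Poly(A)-selected RNA of adult rat ventricular fibroblasts was sequenced as paired reads of 150 bases, per the labels' protocols. There were 12 libraries, 3 for each combination of 2 substrates (tissue culture polystyrene or soft hydrogel) and passage 3 or 6. The groups and replicate numbers were taken from the labels. The labels call the replicates biological and do not say whether they came from separate animals or separate cultures, so p-values measure the spread between these libraries.

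The authors deposited 1 table of raw counts, whole numbers per Ensembl rat gene and library, with no normalization. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.1.0, Cufflinks, Cuffnorm 2.2.1 and the genome build Rnor_6.0. The tool that counted the reads, its strand setting and the release of the gene annotation are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies could therefore be counted for the wrong gene, and this could not be checked per gene. Every row of the table carried a gene identifier. A RefSeq gene table of another assembly, GRCr8, was compared with the identifiers, and 0 of 32623 matched because the table lists no Ensembl identifiers. The files do not pair identifiers with names, so the 30 gene lists fixed before the data were examined, the markers of other cell types among them, were not tested.

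Depth ran from 47834926 to 71464905 counts per library. Replicates were compared by a chi-square test of their counts over genes with at least 20 counts. The statistic per degree of freedom ran from 30.9 to 346, far above sampling noise, and no library was treated as a duplicate. PCR copies were not marked by molecular identifiers, so counts are not independent molecules.

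Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes were filtered with the default settings of filterByExpr by group (minimum count 10, minimum total 15), which left 14660, and libraries were scaled by TMM. A quasi-likelihood F test was run with edgeR on the counts, with the 4 groups in one model and no block. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. Counts per scaled library total (CPM) use TMM-scaled library sizes. Principal components were computed from log2 CPM with a prior count of 2. Shares and library measures were compared by an exact sign-flip test over the 6 pairs (64 arrangements), added after the data were seen, and by an exact permutation test of the substrate labels within each passage, which takes no account of pairs (400 arrangements).

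The comparisons, tests, alternatives and the rule for single genes were fixed before the data were examined. That rule took, per comparison, the genes with the largest change in each direction among those past the threshold, with no overlap between the libraries of the 2 groups and a mean of at least 5 CPM in the higher group; for the interaction, past the threshold and at least 5 in 1 group. It also said that features without a name would be skipped, which here would have removed every gene. After the table was seen, the first 2 genes per direction by the same rule were given by identifier instead. For the interaction, where no gene passed without pairs, the rule was applied to the fit with pairs.

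Whether replicate numbers pair the libraries was checked before calls were compared, by correlating, across genes, the deviations of same-numbered libraries from their group means. Between plastic and soft gel the correlations for numbers 1, 2 and 3 were 0.230, 0.414 and 0.434 at passage 3 and 0.505, 0.555 and 0.717 at passage 6, so the numbers pair the substrates within a passage; the pairing comes from the data, since the labels do not state it. Between passages they were 0.0389, -0.244 and -0.290 on plastic and -0.0210, -0.239 and -0.291 on soft gel, so the numbers do not pair the passages. A fit with a separate term for each passage and number was therefore added for the substrate comparisons. It lowered the common biological coefficient of variation from 0.296 to 0.133. Within single groups this coefficient was 16.3% on plastic and 19.1% on soft gel at passage 3, and 37.1% and 38.6% at passage 6.

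The fits were tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold. The changed genes were drawn from those above a minimum mean count, and each gene had the same spread at both passages. The real libraries spread more at passage 6, so the simulated rates may not hold for the real data. Of the 2-fold changes, the fit without pairs recovered 68.7% in the passage comparison on plastic, 56.7% in the substrate comparison at each passage, 55.2% in the passage comparison on soft gel and 25.4% in the interaction. The fit with pairs recovered 89.6% at passage 3, 79.1% at passage 6 and 68.7% in the interaction. Of the genes called with pairs, 11 of 182, 12 of 166 and 12 of 132 were unchanged ones. Without pairs these were 6 of 120 for passage on plastic, 16 of 121 for passage on soft gel, 0 of 111 and 0 of 97 for substrate at passages 3 and 6, and 0 of 66 in the interaction. Shared libraries were treated by simulating 25 sets of unchanged groups, with variation shared within pairs and again with independent libraries. In these sets, too, each gene had the same spread at both passages.

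The alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2's Wald test, the replicate number as a block, only the 2 groups compared, a minimum 2-fold change, all genes in the principal components, and leaving out each library in turn. Added after the data were seen were the fit with pairs, limma-voom with the pair as a random effect, leaving out both libraries of pair 3 of passage 6, leaving out each pair in turn from the fit with pairs, and principal components without the genes nearly absent from pair 3 of passage 6.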

Results

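Fibroblasts from the ventricles of adult rats were cultured in medium with 20% fetal bovine serum. They were kept on tissue culture polystyrene, the rigid plastic of ordinary culture dishes, or were moved onto a soft hydrogel of poly(ethylene glycol) norbornene, a synthetic polymer network, and the time given for the treatment is 48 h. Cells were taken at passage 3 and at passage 6, a passage being one round of detaching the cells and plating them again. Polyadenylated RNA was sequenced from 12 libraries in 4 groups of 3, which were plastic at passage 3, soft gel at passage 3, plastic at passage 6 and soft gel at passage 6. By its title, the series asks how the stiffness of the growth surface bears on the activation, senescence and inflammatory secretion of cardiac fibroblasts. The deposited table held raw counts for 32623 Ensembl rat genes.

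The plastic libraries held 61840796, 69120841 and 60498549 counts at passage 3 and 65882676, 47834926 and 59249044 at passage 6. The soft gel libraries held 58482104, 57634698 and 58750450 counts at passage 3 and 57482018, 57061019 and 71464905 at passage 6. Levels are given as CPM, counts scaled to a common library total. Between 15927 and 16746 genes had at least 1 count in a library, and 14660 genes passed the filter on low counts. The files do not pair the gene identifiers with gene names, so genes are given by identifier only and no gene group could be followed by name. At most 2 genes in each direction were picked for a comparison, and some of them are also followed in other comparisons.

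The first principal component of the 500 most variable genes held 46.6% of the variance, the second 27.2% and the third 11.5%. The third separated the substrates, with the plastic libraries between -24.1 and -9.78 and the soft gel libraries between 8.66 and 21.2. Within a passage, a plastic and a soft gel library with the same replicate number deviated from their group means in the same genes, so each such couple is called a pair below. The plastic and soft gel libraries of pair 3 at passage 6 stood apart from all others on the second component, at -50.4 and -45.8, where the other 10 libraries lay between -6.02 and 28.7. The median Spearman correlation across genes was 0.986 between libraries of one group, 0.982 between the libraries of a pair, and 0.964 between libraries of different passages.

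**Figure D1:**
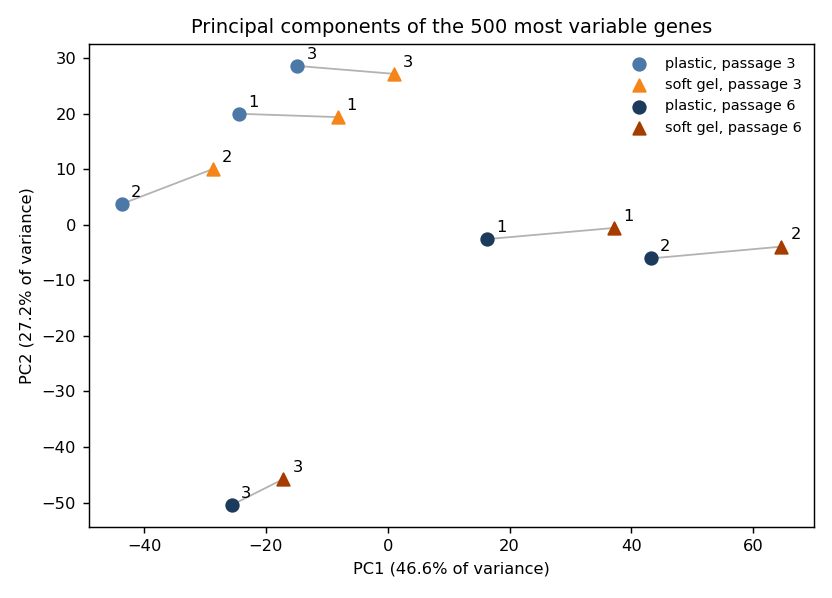
First (horizontal) and second (vertical) principal component scores of the 12 libraries, from log2 CPM of the 500 most variable genes. Circles are plastic and triangles soft gel, numbers are the replicate numbers, and grey lines join the pairs; pair 3 of passage 6 lies at -50.4 and -45.8 on the second component.

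The comparison of passage 6 with passage 3 on plastic asked what further passaging on a stiff surface changed. Replicate numbers did not pair the passages. An effect of passaging can therefore not be told apart from other differences between the cultures used at each passage, here and in later comparisons of the passages. Of 14660 genes, 1124 were higher and 844 lower at passage 6, and 734 of these 1968 genes differed by at least 2-fold. The fit estimates the spread with the libraries of a pair treated as independent, so these p-values may be too small. In simulated data 6 of the 120 genes called in this comparison were unchanged ones. ENSRNOG00000058560 was close to undetected on plastic at passage 3, with 0, 6 and 6 counts, and stood at 209 ± 224 CPM at passage 6 (SD, n = 3). Its log2 fold change was 11.58 ± 1.29 (SE, edgeR adjusted p = 0.000651). ENSRNOG00000016945 rose from 0.0484 ± 0.0421 to 26.0 ± 11.9 CPM, a log2 fold change of 8.98 ± 1.08 (edgeR adjusted p = 0.000896). ENSRNOG00000033581 fell from 12.5 ± 7.26 to 0.464 ± 0.623 CPM, with a log2 fold change of -4.68 ± 1.06 (edgeR adjusted p = 0.0158). ENSRNOG00000015093 fell from 11.6 ± 6.83 to 0.534 ± 0.525, with a log2 fold change of -4.40 ± 0.90 (edgeR adjusted p = 0.0101). The count of genes was 1062, 965 and 878 without plastic library 1, 2 or 3 of passage 3, and 1095 without plastic library 3 of passage 6; ENSRNOG00000033581 missed the threshold without plastic library 3 of either passage, at adjusted p = 0.0564 and 0.0575. With limma-voom and the pair as a random effect none of these 4 genes passed, with adjusted p between 0.0742 and 0.215, while over the other alternatives the highest adjusted p was 0.0575.

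At passage 3, the comparison of soft gel with plastic asked what 48 h on a soft surface changed in cells passaged few times. With the libraries treated as independent, 165 genes were higher and 172 lower on soft gel, and 113 of the 337 differed by at least 2-fold. The balance between the directions depended on the scaling and the libraries, with 186 higher and 142 lower under DESeq2's size factors, 628 and 572 in DESeq2's own test and 52 and 29 without soft gel library 2 of passage 3. With a term for each pair, 1297 genes were higher and 1452 lower, and all 337 genes were among these 2749 in the same direction. The 2749 became 1093, 1156 and 1050 without pair 1, 2 or 3 of passage 3, with 643 higher and 513 lower without pair 2. ENSRNOG00000009465 rose from 0.357 ± 0.181 CPM on plastic to 11.5 ± 1.40 on soft gel (SD, n = 3), a log2 fold change of 5.0 ± 0.96 (edgeR adjusted p = 0.0291). ENSRNOG00000002947 rose from 23.6 ± 8.56 to 232 ± 92.9, a log2 fold change of 3.30 ± 0.70 (edgeR adjusted p = 0.0389). ENSRNOG00000013916 fell from 9.40 ± 2.86 to 0.448 ± 0.337, a log2 fold change of -4.39 ± 0.72 (edgeR adjusted p = 0.0176). ENSRNOG00000033528 fell from 112 ± 25.5 to 27.8 ± 6.31, a log2 fold change of -2.01 ± 0.23 (edgeR adjusted p = 0.00767).

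All 4 of these genes passed in the fit with pairs, where the log2 fold changes were 5.04 ± 0.33 for ENSRNOG00000009465, 3.30 ± 0.22 for ENSRNOG00000002947, -4.50 ± 0.47 for ENSRNOG00000013916 and -2.01 ± 0.07 for ENSRNOG00000033528. Without pairs, the 337 genes became 55, 41 and 38 without plastic library 1, 2 or 3 of passage 3 and 34, 81 and 57 without the soft gel library of the same number. They became 538 without plastic library 3 of passage 6 and 1036 without both libraries of pair 3 of passage 6, which enter this comparison through the shared estimate of the spread. With 1 of the 6 libraries of passage 3 left out, ENSRNOG00000009465 and ENSRNOG00000002947 missed the threshold each time, with adjusted p between 0.0671 and 0.168, and ENSRNOG00000013916 missed it in 5 of 6 cases, at up to 0.103. ENSRNOG00000033528 passed under all 20 alternatives run, at an adjusted p of 0.0442 or lower.

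At passage 6, the same comparison asked what the soft surface changed in cells passaged more often. Without pairs, 714 genes were higher and 746 lower on soft gel, and 510 of the 1460 differed by at least 2-fold. With pairs, 1805 were higher and 1845 lower, and 1458 of the 1460 were among these 3650 genes in the same direction. ENSRNOG00000019500 rose from 0.122 ± 0.119 to 5.73 ± 2.45 CPM (SD, n = 3), a log2 fold change of 5.48 ± 1.32 (edgeR adjusted p = 0.0256). ENSRNOG00000002802 rose from 3.32 ± 2.45 to 65.1 ± 29.7, a log2 fold change of 4.29 ± 0.59 (edgeR adjusted p = 0.00173). ENSRNOG00000003171 fell from 16.5 ± 24.6 to 0.142 ± 0.190, a log2 fold change of -6.90 ± 1.53 (edgeR adjusted p = 0.0180). ENSRNOG00000013916, which had fallen on soft gel at passage 3, fell from 10.3 ± 2.56 to 0.0931 ± 0.0979, a log2 fold change of -6.83 ± 0.84 (edgeR adjusted p = 0.00133).

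ENSRNOG00000002802 and ENSRNOG00000013916 passed at passage 6 under all 20 alternatives run. ENSRNOG00000019500 missed the threshold without plastic library 1, plastic library 2 or soft gel library 3 of passage 6, at adjusted p = 0.0712, 0.0690 and 0.0560, and ENSRNOG00000003171 without soft gel library 2 or 3 of passage 6, at 0.0549 and 0.0526. The level of ENSRNOG00000003171 on plastic at passage 6 was 44.8 CPM in library 1 against 4.03 and 0.697 in libraries 2 and 3, and without plastic library 1 its log2 fold change was -4.07 (edgeR adjusted p = 0.0467). Over all alternatives the adjusted p ran from 0.000480 to 0.0712 for ENSRNOG00000019500 and from 7.57e-06 to 0.302 for ENSRNOG00000003171. The 1460 genes became 878 without plastic library 2 and 908 (467 higher and 441 lower) without soft gel library 3 of passage 6. With only the 6 libraries of passage 6 in the fit there were 189, where the same fit at passage 3 gave 2109.

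**Figure D2:**
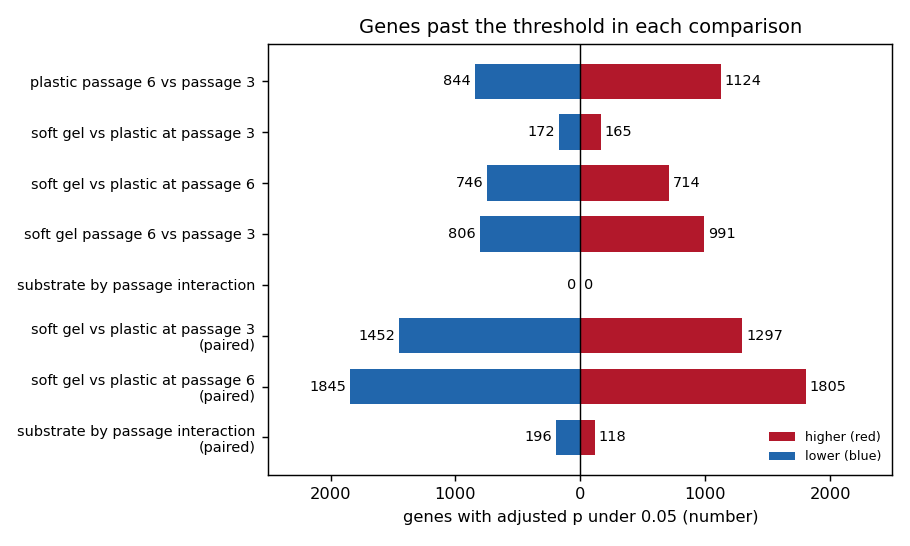
Number of genes with adjusted p under 0.05 (horizontal axis) in each comparison, with genes higher in the first-named group to the right and lower ones to the left. For the substrate by passage interaction, right means a larger soft gel over plastic log2 fold change at passage 6; the rows marked paired come from the fit with a term for each pair, where the interaction had 314 genes.

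The substrate differences at the 2 passages, which share no library, were then set side by side. Without pairs, 121 genes were higher and 121 lower on soft gel at both passages, where independent lists would share 8.04 and 8.75, and no gene passed in opposite directions. Both lists use 1 shared estimate of the spread, and at both passages highly expressed genes were called more often. Each may raise the number shared above that of independent lists, here and in the later comparisons with such lists. With DESeq2's size factors in edgeR the shared genes were 138 higher and 99 lower. With pairs, 825 genes were higher and 845 lower at both, against 160 and 183 for independent lists, and 36 passed in opposite directions. These 1670 shared genes became 805, 904 and 749 without pair 1, 2 or 3 of passage 3, and the 36 became 15, 13 and 10, or 62 and 57 without pair 1 or 2 of passage 6. ENSRNOG00000013916 and ENSRNOG00000033528 were lower at both, the second with a log2 fold change of -2.01 ± 0.23 at passage 3 and -1.50 ± 0.23 at passage 6. Across the 14660 genes, the log2 fold changes of the 2 passages had Pearson's r = 0.536 and Spearman's rho = 0.545 without pairs; genes are not independent replicates. In 25 simulated sets of unchanged groups r lay between -0.0246 and 0.0343. The 242 shared genes became 49, 38 and 33 without plastic library 1, 2 or 3 of passage 3, 31, 72 and 48 without the soft gel library of the same number, 367 without plastic library 3 of passage 6 and 471 without both libraries of that pair.

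**Figure D3:**
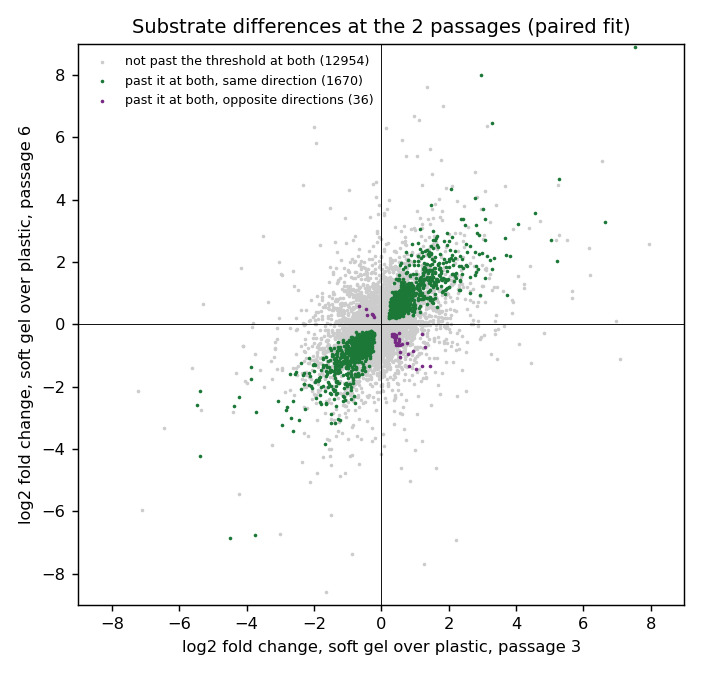
Log2 fold change of soft gel over plastic at passage 3 (horizontal) and at passage 6 (vertical) for 14660 genes, from the fit with pairs, 1 point per gene. Green points passed the threshold at both passages in the same direction (1670 genes), purple points at both in opposite directions (36 genes), and grey points are all others.

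Whether the substrate difference depended on passage was tested as an interaction. Without pairs, edgeR called 0 genes, with 1044 genes at an unadjusted p under 0.05 where 733 would come by chance, and DESeq2 called 94. With pairs, edgeR called 314 genes. The substrate difference was larger in size at passage 6 for 207 of them and larger at passage 3 for 71, and 36 passed in opposite directions at the 2 passages. The fit pools the spread of a gene over both passages, and the libraries of passage 6 spread more. This may have favoured calls with the larger difference at passage 6, so 207 against 71 does not by itself show a stronger response there. ENSRNOG00000001469, among the more abundant genes, stood at 1491 ± 931 CPM on plastic and 1402 ± 524 on soft gel at passage 3, and at 4884 ± 4703 on plastic and 293 ± 256 on soft gel at passage 6 (SD, n = 3). Its log2 fold change on soft gel with pairs was 0.06 ± 0.21 at passage 3 and -3.89 ± 0.23 at passage 6, a difference of -3.96 ± 0.30 (edgeR adjusted p = 0.00188). ENSRNOG00000003171 was lower on soft gel at both passages, with log2 fold changes of -3.75 ± 0.26 and -6.76 ± 0.35, a difference of -3.02 ± 0.45 (edgeR adjusted p = 0.0168). ENSRNOG00000021735 was higher on soft gel at both, at 1.46 ± 0.16 and 3.82 ± 0.19, a difference of 2.35 ± 0.24 (edgeR adjusted p = 0.00374). ENSRNOG00000018735 was lower on soft gel at both, at -3.87 ± 0.31 and -1.36 ± 0.27, a difference of 2.51 ± 0.40 (edgeR adjusted p = 0.0212). It was nearly absent from pair 3 of passage 6, with 0.289 CPM on plastic and 0.126 on soft gel, against 11.5 to 37.5 in the other 4 libraries of passage 6.

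None of these 4 genes passed the interaction test without pairs in edgeR, where the adjusted p was 0.448 for ENSRNOG00000001469, 0.832 for ENSRNOG00000003171, 0.261 for ENSRNOG00000021735 and 0.912 for ENSRNOG00000018735. Without pairs the interaction of ENSRNOG00000003171 was -3.10 on the log2 scale, which became -0.274 without plastic library 1 of passage 6 and -5.22 without soft gel library 1 of passage 6. In the fit with pairs its call was lost without pair 1 of passage 6, where the difference was -2.41 ± 0.73 (edgeR adjusted p = 0.133), and without pair 1 or 2 of passage 3 (edgeR adjusted p = 0.0572 and 0.0910). That of ENSRNOG00000018735 was lost without pair 1 or 3 of passage 3 (edgeR adjusted p = 0.127 and 0.138). DESeq2 without pairs called ENSRNOG00000021735 (adjusted p = 0.000249), whose adjusted p reached 0.678 over the other alternatives. With limma-voom and the pair as a random effect, 83 genes passed, among these 4 only ENSRNOG00000001469 (adjusted p = 0.0387), whose adjusted p reached 0.893 over the other alternatives. The 314 genes of the fit with pairs became 34, 43 and 33 without pair 1, 2 or 3 of passage 3, and 459, 476 and 145 without pair 1, 2 or 3 of passage 6. Without pairs in the model, the count of 0 became 4, 4 and 2 without plastic library 1, 2 or 3 of passage 6 and 1 and 9 without soft gel library 1 or 2 of passage 6.

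**Figure D4:**
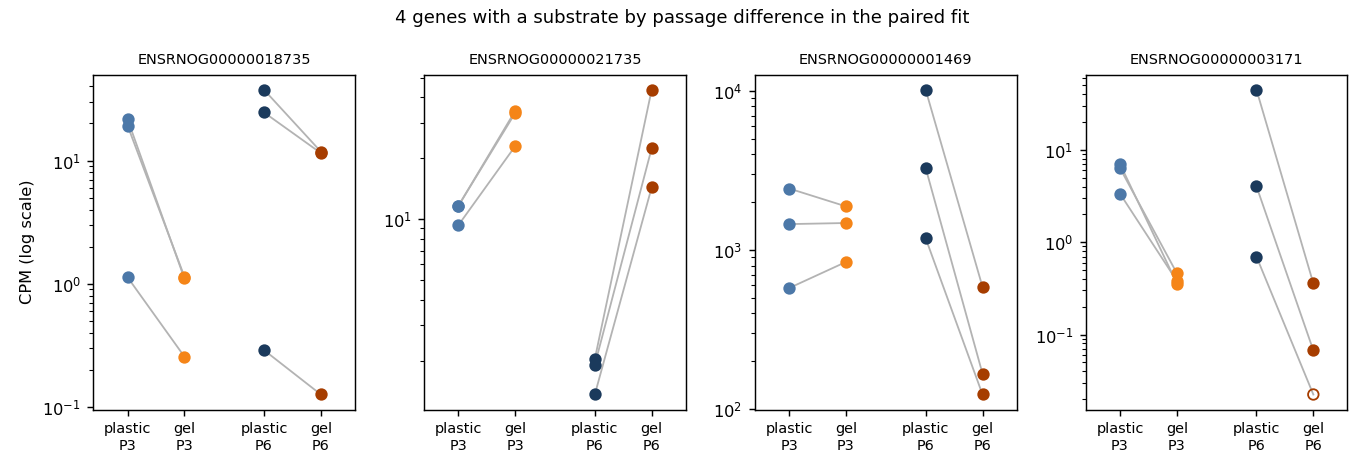
CPM (vertical, log scale) of 4 genes with a substrate by passage difference in the fit with pairs, 1 point per library, with grey lines joining the pairs. The open circle marks a count of 0, drawn below the lowest other value; ENSRNOG00000001469 is lower on soft gel in all 3 pairs of passage 6, with a log2 fold change of -3.89.

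The passage comparison on soft gel asked how passage 6 differed from passage 3 in cells that had then spent 48 h on the soft surface. There were 991 genes higher and 806 lower at passage 6, of which 709 differed by at least 2-fold. As on plastic, the p-values may be too small because the fit treats the libraries of a pair as independent. In simulated data 16 of the 121 genes called in this comparison were unchanged ones. ENSRNOG00000002548 rose from 0.269 ± 0.150 to 40.3 ± 45.5 CPM (SD, n = 3), a log2 fold change of 7.21 ± 1.11 (edgeR adjusted p = 0.00295). ENSRNOG00000046834 rose from 1.53 ± 1.42 to 153 ± 187, a log2 fold change of 6.63 ± 1.53 (edgeR adjusted p = 0.0190), with 89.3, 363 and 5.84 CPM in soft gel libraries 1, 2 and 3 of passage 6. This gene and ENSRNOG00000018735 are among 102 genes with at least 1 CPM in each of the other libraries of passage 6 and a mean CPM at least 20 times lower in pair 3 of that passage. ENSRNOG00000019120 fell from 34.8 ± 17.3 to 0.652 ± 0.385, a log2 fold change of -5.71 ± 0.82 (edgeR adjusted p = 0.00196), and ENSRNOG00000015093, which had also fallen on plastic, from 29.96 ± 14.3 to 0.650 ± 0.665, a log2 fold change of -5.54 ± 0.93 (edgeR adjusted p = 0.00467). The 1797 genes became 802, 1189 (564 higher and 625 lower) and 955 without soft gel library 1, 2 or 3 of passage 3, 1092 without soft gel library 2 of passage 6 and 1045 with only the 6 soft gel libraries in the fit. ENSRNOG00000046834 missed the threshold without soft gel library 1 or 2 of passage 3 or soft gel library 2 of passage 6, at adjusted p = 0.0808, 0.0703 and 0.0521, and its adjusted p ran from 1.10e-05 to 0.266 over all alternatives; with limma-voom and the pair as a random effect ENSRNOG00000002548 missed it at 0.193, with 0.0213 the highest over its leave-one-out fits.

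The passage differences on plastic and on soft gel had 535 higher and 413 lower genes in common, against 76.0 and 46.4 for independent lists, and 3 genes passed in opposite directions. Pearson's r across genes was 0.712 and Spearman's rho 0.646. Since the pairs link the plastic and soft gel libraries of a passage, unchanged groups were simulated with variation shared within pairs, and these gave r = 0.553 on average over 25 sets. The observed covariance of the log2 fold changes was 0.642, against a simulated mean of 0.151 and a highest simulated value of 0.171.

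The study design also allows the question of whether soft gel at passage 6 moved genes against the direction of their passage difference on plastic. ENSRNOG00000058560, which had risen with passage on plastic, was lower on soft gel at passage 6, at 2.51 ± 1.81 CPM (SD, n = 3) against 209 ± 224 on plastic, a log2 fold change of -6.36 ± 0.93 (edgeR adjusted p = 0.00246). On soft gel it still rose with passage (6.71 ± 1.55, edgeR adjusted p = 0.0187). The other genes named for passage on plastic passed here only with pairs or not at all. With pairs, ENSRNOG00000016945 rose further on soft gel (0.93 ± 0.22, edgeR adjusted p = 0.0135). ENSRNOG00000033581 was opposed (1.72 ± 0.49, edgeR adjusted p = 0.0301), and ENSRNOG00000015093 did not pass (edgeR adjusted p = 0.404). Without pairs, genes that passed both tests in opposite directions numbered 276. Of these, 190 were higher with passage and lower on soft gel and 86 the reverse, where independent lists would share 57.2 and 41.1. Genes that passed both in the same direction numbered 148, with 86 higher and 62 lower in both, where independent lists would share 54.7 and 42.9. With pairs, 481 genes were opposed and 307 moved in the same direction. The 481 became 205, 248 and 175 and the 307 became 96, 122 and 83 without pair 1, 2 or 3 of passage 3, and the 481 became 320 without pair 3 of passage 6.

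Both of these comparisons use the plastic libraries of passage 6, which by itself gives a negative relation. Across genes the log2 fold changes had r = -0.0934 and rho = -0.0463, against a mean r of -0.352 in simulated unchanged groups with variation shared within pairs. The observed covariance was -0.0707, within the range of -0.0722 to -0.0586 of these simulated sets, whose mean was -0.0645. With independent libraries the simulated covariance ran from -0.155 to -0.120. In all simulated sets each gene had the same spread at both passages, whereas the real libraries spread more at passage 6. The sets therefore cannot tell how negative the shared libraries alone would make the covariance. No opposing relation across all genes was shown beyond the shared libraries. The simulated sets gave no gene that passed both tests. With all groups unchanged, hardly any gene could pass even a single test, so this does not bear on the 276 opposed genes. With 3 plastic libraries at passage 6 the shared group could not be split into parts of at least 2, and part of the excess of opposed genes over independent lists may come from the shared libraries. The 276 opposed genes became 160, 160 and 150 without plastic library 1, 2 or 3 of passage 3, 180 without plastic library 3 of passage 6 and 181 without both libraries of that pair.

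The 10 most abundant genes of a library took 12.1% ± 0.224 of the counts on plastic and 11.2% ± 0.0663 on soft gel at passage 3, and 12.8% ± 1.95 and 10.1% ± 0.731 at passage 6 (SD, n = 3). The share was lower on soft gel in 6 of 6 pairs, with a mean difference of -1.79 points. The exact two-sided sign-flip permutation test over the pairs gave p = 0.03125, the smallest its 64 arrangements can give, and a Benjamini-Hochberg adjusted p = 0.0781 over 5 measures, so it did not pass. The normalization factor was 0.104 higher on soft gel in 6 of 6 pairs, with the same 2 values in the exact test. The share of whichever gene was most abundant in a library was lower in 5 of 6 pairs, with a mean difference of -0.557 points (exact sign-flip p = 0.0625, adjusted p = 0.104). That gene differed between libraries, also within pairs, so this measure does not follow a single gene. Total counts and the number of genes detected each gave an exact sign-flip p = 0.844. An exact permutation within passages that leaves the pairs out of account gave adjusted p = 0.0125 for the first 2 measures and 0.025 for the most abundant gene.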

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

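The tests of pooled spread and of the size of the shared substrate difference were chosen after the results they concern were seen; the thinning test and the splits of 6 libraries were not. The splits of pairs for the interaction, and the look at splits that part all pairs, follow a pairing and a fit that were added after the data were seen.

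A difference between passages in the response to substrate was found by the interaction test, with 314 genes past the threshold in the fit with pairs and 0 without pairs in edgeR, where 1044 had an unadjusted p under 0.05 and DESeq2 called 94. ENSRNOG00000001469 had the most negative difference under the rule for single genes, -3.96 ± 0.30 on the log2 scale. Of the 314 genes, 207 had the larger substrate difference at passage 6, 71 at passage 3, and 36 passed in opposite directions. The spread was pooled over both passages and was wider at passage 6, which may have favoured the 207. The fit with pairs was added after the data were seen, and the count depends on single pairs, with 33 genes without pair 3 and 34 without pair 1 of passage 3, 43 without pair 2 of passage 3, 145 without pair 3 of passage 6, and 459 without pair 1 and 476 without pair 2 of passage 6. In simulated data, 12 of the 132 genes that the fit with pairs called for the interaction were unchanged ones. Those data had the same spread at both passages, unlike the real libraries, so this share may not hold for the 314 genes.

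The libraries of each comparison were also split in all other ways into groups of 3, which makes 10 splits, too few for a share under 0.05. In each of the passage and substrate comparisons 1 of the 10 splits, the real one itself, reached the real count. That count and the highest other were 1968 and 0 for passage on plastic, 337 and 0 for substrate at passage 3, 1460 and 2 for substrate at passage 6, and 1797 and 0 for passage on soft gel. For the interaction, the 6 pairs were split between the passages. Without pairs in the model the real split gave 0, as did the highest other, so 10 of 10 gave as many; with pairs the real split gave 314 and the highest other 0, so 1 of 10 did. For the substrate comparisons, 3 of the other splits also parted all 3 pairs, and the highest count among them was 0. Every other split, of libraries or of pairs, mixed the real groups. A real difference then widens the spread within the mixed groups, so low counts were likely in advance. The splits therefore cannot tell whether the real counts exceed chance.

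More genes passed in the substrate comparison at passage 6 than at passage 3, 1460 against 337 without pairs. Sequencing depth was argued against, since with all libraries thinned to 47834926 counts the ratio of the counts of genes was 4.16, against 4.33 without thinning. The libraries of passage 6 spread more, and a spread pooled over both passages may have raised the count at passage 6 and lowered it at passage 3, since with only the 2 groups compared in each fit the ratio was 0.0896. A somewhat larger substrate difference at passage 6 also stays open, since the SD of the log2 difference that pairs share was 0.537 at passage 6 against 0.479 at passage 3, a ratio of 1.12 that ran from 1.06 to 1.15 with 1 pair left out. With pairs in the model the ratio of the counts of genes was 1.33.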

How the results depend on the processing

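The alternatives with pairs, the pair as a random effect, the removal of single pairs and the sign-flip test were chosen after the data were seen. No gene named under the rule for single genes changed direction in its own comparison under any alternative run. The direction of other genes was not followed. DESeq2's size factors moved no count by over 1.5 times, shifted the median of all genes by less than 0.1 on the log2 scale and left the interaction at 0 genes, but turned the balance of substrate at passage 3 from 165 higher and 172 lower to 186 and 142, and that of shared genes from 121 of each to 138 and 99. The balance also turned for substrate at passage 6 with only the 2 groups compared (100 higher, 89 lower) and without soft gel library 2 (614, 606) or 3 (467, 441) of passage 6, and for passage on soft gel without soft gel library 2 of passage 3 (564, 625). Without a filter the interaction had 1 gene.

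DESeq2's Wald test gave 1200 genes for substrate at passage 3, 2204 at passage 6, 94 for the interaction, 693 shared substrate genes and 456 opposed genes. With only the 2 groups compared there were 2109 genes for substrate at passage 3, 189 at passage 6 and 1045 for passage on soft gel, where each fit uses its own spread and fewer samples. With a 2-fold minimum the shared genes were 77 and the opposed genes 91, since fewer genes qualify. Over all genes the first principal component held 32.0% of the variance.

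With the replicate number as a block across passages there were 629 genes for substrate at passage 3 and 435 shared genes; this block moved no other count by over 1.5 times and ended 1 call, ENSRNOG00000046834 for passage on soft gel (adjusted p = 0.0650). With pairs within a passage there were 2749 and 3650 genes for substrate at passages 3 and 6, 314 for the interaction, 1670 shared and 481 opposed. With limma-voom and the pair as a random effect (correlation 0.462) these were 2407, 3434, 83, 1339 and 460. In the fit without a term for pairs, leaving out pair 3 of passage 6 gave 1036 genes for substrate at passage 3, 2 for the interaction, 471 shared and 181 opposed. In that fit passage on plastic had 1533, substrate at passage 6 1009 and passage on soft gel 2058.

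With 1 library left out the count ran from 878 to 2127 for passage on plastic, 34 to 538 for substrate at passage 3, 878 to 1448 at passage 6, 802 to 2013 for passage on soft gel, 0 to 9 for the interaction, 31 to 367 for shared genes and 150 to 326 for opposed genes. Apart from the values above where a cause is named, the cause was not tested. Of the values of single genes under an alternative, fits with pairs and 1 pair removed not counted, 343 kept their side of the threshold, 39 lost the call and 6 gained it. The gene list tests and their alternatives were not run, because no identifier could be matched to a name, and neither was the pseudocount alternative, which applies to normalized values. In the third of genes with the lowest expression 0.532% were called for substrate at passage 3, against 4.09% in the third with the highest.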

Other observations

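For pair 3 of passage 6, the depth, label swap and component tests were chosen after the pattern was seen. So were the substrate test on the genes missing from that pair and their correlation over passage 3 alone. Their correlation over the other 10 libraries also rests on a pair first seen to stand apart in these data.

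A set of 102 genes was present at 1 CPM or more in the other 4 libraries of passage 6 and at least 20 times lower, by mean CPM, in pair 3 of that passage. ENSRNOG00000046834 and ENSRNOG00000018735 are in this set. The same criterion gave 0 to 3 genes for each of the other 5 pairs. The median of the set was 0.128 CPM on plastic and 0.265 on soft gel in pair 3 of passage 6, and ran up to 19.2 CPM in soft gel library 2 of passage 6, where the set took 0.667% of the counts. It was also low in pair 2 of passage 3, at 0.313 CPM on plastic and 0.887 on soft gel. In every pair the median was higher on soft gel than on plastic, by 1.82-fold to 2.84-fold (6 of 6 pairs, exact two-sided sign-flip permutation test, p = 0.03125, the smallest the 64 arrangements can give). Over both passages 93 of the 102 genes had a mean log2 fold change above 0 on soft gel in the fit with pairs, with a median log2 fold change of 1.21 (quartiles 0.618 and 1.64). At each passage 58 of them passed the threshold as higher and 4 as lower with edgeR and pairs; without pairs edgeR called 0 at either passage, with 4 genes at an unadjusted p under 0.05 at passage 3 and 2 at passage 6, and DESeq2 called 2 and 0.

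Pair 3 of passage 6 stood apart from the other 10 libraries on the second principal component. Lower depth was argued against, since the smaller of its 2 totals was 59249044 counts, above the lowest of the other passage 6 libraries, 47834926. A swap with a passage 3 pair was argued against as well, since 0 of the 3 pairs of passage 3 lay closer to the other passage 6 libraries than to their own passage. Of the 102 genes, 100 were among the 500 most variable, but they do not account for the position on the second component. With them removed, the pair lay 29.8 from the nearest other library on that component (39.75 with them), against an SD of 10.2 among the other 10. Over those 10 the median of the set had Spearman's rho = 0.976 with the first component and -0.503 with the second. Both components were computed with the set included, so these values cannot tell which component the set follows. On the components without the set, the lowest of those 10 on the second were the libraries of pair 2 of passage 3. They lay at -10.4 on plastic and -3.76 on soft gel, and the set was also low in them. What sets pair 3 of passage 6 apart on the second component, and whether it is tied to the set, stays open. For the 102 genes themselves, a candidate explanation is a second cell population, or a gene programme switched on together, whose share differs between cultures: they had a median pairwise Spearman correlation of 0.903 over the other 10 libraries, and 0.829 over the 6 libraries of passage 3, which took no part in choosing them, against highest values of 0.0667 and 0.0857 in 2000 random sets matched on expression. Which of the 2 it is stays open, because without gene names no marker could be followed, and whether the pairs come from different animals is not stated. The random sets were matched on expression only, not on variability or on a joint shift in a pair, so exceeding them says little about the cause. Part of the correlation over passage 3 may come from the substrate, since the median of the set was higher on soft gel in every pair.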
